A study of Mus musculus with 24 samples.

How the data were processed

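Expression was measured in 24 samples of mouse total RNA on Illumina MouseRef-8 v2 BeadChips. The 12 groups, each of 2 arrays that the labels call biological replicates, were male and female ES cells (ESCm and ESCf), female and male EpiSCs (EpiSCf of OG2 and EpiSCm of GOF18 background), and F9 and P19 embryonal carcinoma cells. The other 6 are labelled as overexpressing wild-type Sox2: F9-Sox2, P19-Sox2, Epi-Sox2f, EpiSox2mL2 in EpiSC medium, and EpiSox2mE1 and EpiSox2mE2 in ESC medium. Per the labels, 300 ng of RNA entered each amplification and hybridisation lasted 18 h. In vitro transcription took 10 h per the sample labels and 12 h per the series description. The submitters' processing notes name BeadStudio 3.2, RMA and lumi.

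The deposited table of non-normalized values gave an intensity for each of 25697 probes on each array, together with a deposited detection p-value. The authors also deposited processed log2 values, whose columns shared a median of 3.68 and followed the order of the signals within each array. The labels do not say how these log2 values were made, so the intensities were the starting point and the authors' log2 values served as an alternative. Over the tested genes they correlated at 0.987 with the values used here. No deposited column was left unmapped.

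Background was removed with the normexp model of limma 3.58.1 in R 4.3.3, with background mean and spread inferred from the detection p-values, an offset of 16, quantile normalization over the 24 arrays and a log2 transform. Of the probes, 23978 carried 1 gene symbol and 1719 had none and were not tested. Entrez identifiers of 23962 named probes matched a RefSeq annotation of GRCm38.p6, which served for names and chromosomes alone. A probe was kept if its detection p was under 0.01 on both arrays of at least 1 group, which left 13082 probes, 12324 of them named. Each gene was represented by its kept probe with the highest mean, for 8932 genes, of which 2395 had more than 1 kept probe. The gene T was not measured.

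Limma fitted 1 mean per group over all 24 arrays, with 12 residual and 5.58 prior degrees of freedom. The 14 comparisons and 7 differences of effects were tested with moderated statistics and Benjamini-Hochberg adjustment within each, and a gene was called at adjusted p under 0.05. Where neither array of the dimmer group detected a gene, its fold is given as a lower bound, the brighter mean over the detection limit of the arrays, while the log2 value is that of the fit.

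Gene lists were fixed before the data were examined, as were the comparisons, the threshold and the rule for named genes. They cover core pluripotency, naive pluripotency, primed pluripotency, mesendoderm, neural and ectoderm, extraembryonic endoderm, trophoblast, fibroblast and feeder cells, germ line, 2-cell-like, DNA methylation, FGF-ERK targets, LIF-STAT3, Nodal-Activin, Wnt targets, BMP targets, glycolysis and hypoxia, oxidative phosphorylation, epithelial and mesenchymal, p53 and apoptosis, cell cycle, imprinted, Sox family, and X-linked silencing and Y-linked genes. Each was tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the 24 lists of a comparison. List results give members called up and down, the median log2 change, and counts with p-values adjusted over the list alone. A list not mentioned for a comparison was not called there.

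Named genes were Sox2, Pou5f1, Nanog, Klf4, Esrrb, Zfp42 and Fgf5 in every comparison, and the 5 largest rises and 5 largest falls among called genes that both arrays of the higher group detected and whose arrays did not overlap. Up to 4 called members with the largest change came from each list that is summarised. For differences of effects the 5 largest in each direction were named. Every such result was recomputed under the alternatives of the closing section.

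The axis of pluripotent state used the 2591 genes called at least 2-fold between EpiSCf and ESCf. Each array's position is the least-squares slope of its distance from the ESCf mean on the EpiSCf distance. Overlaps of calls were set against the number expected by independence in each direction, and comparisons that share control arrays against 100 draws of unchanged groups.

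In data simulated from the observed means and spreads with 200 changed genes, the test recovered a median of 33.6% of 1.5-fold, 85.8% of 2-fold and 98.5% of 4-fold changes over the 14 comparisons, with 4 to 19 false calls. A shifted list was called in 14 of 14 comparisons and unshifted lists in 0 of 322. A simulated array midway on the axis was placed at 0.50 and an unchanged EpiSCf array at 0.99. Raw scans, bead-level values and probe sequences were not used here.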

Results

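The series holds 24 arrays of mouse pluripotent lines in 12 groups of 2, set out to compare ES cells, EpiSCs and embryonal carcinoma cells with and without Sox2 overexpression. Median signal was 119 to 152 on 16 arrays and 90.2 to 101 on the 8 arrays of the GOF18 male EpiSC family.

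Sox2 rose on the probe kept for the gene in 5 of the 6 groups labelled as overexpressing it. Its level increased 2.30-fold in F9-Sox2 over F9 EC (log2 1.20, SE 0.13) and 1.76-fold in P19-Sox2 over P19 EC (0.82, SE 0.13). In the male EpiSC background it increased 1.90-fold in EpiSox2mL2, 2.26-fold in EpiSox2mE1 and 2.45-fold in EpiSox2mE2, with 2 arrays in each group. The arrays labelled Epi-Sox2f showed no rise over EpiSCf (log2 -0.18, SE 0.13, adjusted p = 0.32). The other Sox2 probe also rose in EpiSox2mL2 (log2 0.82), EpiSox2mE1 (0.74) and EpiSox2mE2 (0.95). It fell in the arrays labelled Epi-Sox2f (log2 -1.14, adjusted p = 5.8e-05) and was not called in F9-Sox2 (0.07) or P19-Sox2 (-0.39). That probe lay at log2 4.76 in EpiSCm, where neither array detected it, against 10.68 in ESCm.

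**Figure D1:**
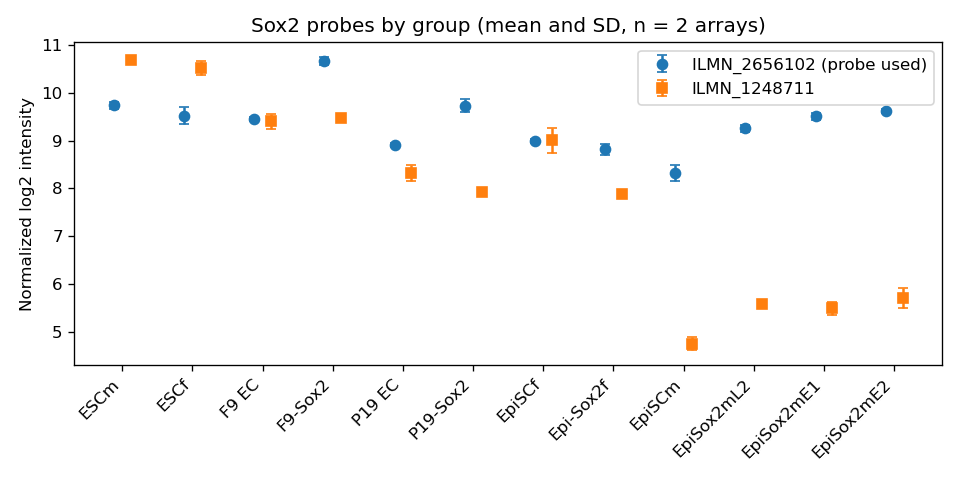
Normalized log2 intensity of the Sox2 probes in the 12 groups, as mean and SD of 2 arrays. The probe kept for the gene stood at 10.66 in F9-Sox2 and at 8.81 in the arrays labelled Epi-Sox2f.

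Sex-linked transcripts gave the second label check. Xist, the RNA that coats an inactive X chromosome, was detected on both arrays of EpiSCf (log2 7.97) and of Epi-Sox2f (7.69) and on neither array of ESCf (5.14). Eif2s3y, a Y-linked translation factor, stood at log2 9.74 in ESCm, 9.33 in P19 EC and 8.01 in EpiSCm. It lay at background in the female groups and also in F9 EC (4.44) and F9-Sox2 (4.47), which the labels call male. Usp9y, a Y-linked deubiquitinase, was at least 3.69-fold higher in EpiSox2mE2 than in EpiSox2mE1 (log2 2.90, SE 0.13), and at least 3.44-fold higher in EpiSox2mL2 than in EpiSCm. Replicate arrays of a group correlated at 0.985 to 0.995 over the 8932 tested genes.

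Female epiblast stem cells lost the transcripts of naive pluripotency and gained those of the postimplantation epiblast (EpiSCf against ESCf, 2 arrays each). The ES-cell marker Dppa5a was at least 686-fold lower (log2 -10.07, SE 0.17), and the oocyte and embryo factor Ooep at least 294-fold lower (-8.97, SE 0.12). Dnmt3l, a cofactor of de novo DNA methylation, was at least 204-fold lower, the pluripotency-associated Dppa4 at least 120-fold lower and the galectin Lgals3 at least 108-fold lower (log2 -8.07, -7.99 and -7.99). The orphan receptor Esrrb was at least 125-fold lower (log2 -7.85, SE 0.16), and the transcription factor Klf4 at least 26.2-fold lower (-5.77, SE 0.20). Zfp42, a zinc-finger marker of naive cells, fell less (log2 -3.73, SE 0.19). Nanog and Pou5f1, at the core of the pluripotency network, fell by 0.87 and 0.76 log2 units, and Sox2 by 0.53 (adjusted p = 0.0017). A second Pou5f1 probe was not called (-0.10), and the second Sox2 probe fell further (adjusted p = 1.5e-07). The largest rises were the neuropeptide Npy (at least 85.6-fold, log2 7.45, SE 0.13), the sulfotransferase Chst1 (at least 59.7-fold, 6.92, SE 0.18) and the neuronal membrane protein Slitrk5 (at least 39.1-fold, 5.96, SE 0.19). Fgf5, the standard marker of primed epiblast, increased at least 28.2-fold (log2 5.57, SE 0.19) and the zinc-finger gene Zfp608 at least 25.6-fold (5.56, SE 0.16). Pou3f1, an epiblast POU factor, and the carbonic anhydrase Car4 increased 25.6-fold and 26.6-fold. Fgf8, a primitive-streak growth factor, increased at least 20.7-fold (log2 4.88, SE 0.20), and the imprinted growth regulator Grb10 13.4-fold (3.75, SE 0.12).

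Germ-line and early-embryo genes fell with the naive ones. Xlr4a was at least 114-fold lower (log2 -7.36, SE 0.14), Tex19.1, which guards germ cells against transposons, 70.9-fold lower, and the 2-cell-stage gene Zscan4c at least 39.2-fold lower. The X-linked homeobox gene Rhox5 was at least 126-fold lower, the trophoblast regulator Tfap2c at least 65.5-fold lower, and Acta2, a smooth-muscle actin, at least 83.2-fold lower (log2 -7.81, -6.75 and -6.84). Xist increased at least 4.94-fold (log2 2.83, SE 0.28). Limma's test called 5379 of 8932 genes, 2940 up and 2439 down (3547 and 1871 under median scaling), of which 2591 moved at least 2-fold. By list, naive pluripotency had 1 of 22 up and 20 down (median -4.13, adjusted p = 6.1e-16), germ line 0 of 11 up and 10 down (median -3.47, adjusted p = 4.5e-08), trophoblast 1 of 14 up and 12 down (median -2.16, adjusted p = 5.7e-07) and 2-cell-like 0 of 9 up and 9 down (median -2.31, adjusted p = 7.4e-07). Primed pluripotency had 18 of 21 up and 3 down (median 2.44, adjusted p = 2.3e-06). The extraembryonic endoderm list had 1 of 15 up and 10 down, or 1 and 11 adjusted over the list alone (median -1.36, adjusted p = 0.0017), fibroblast and feeder cells 2 of 16 up and 11 down (median -1.33, adjusted p = 0.0022, and adjusted p = 0.083 with an estimated correlation), and LIF-STAT3 3 of 14 up and 8 down (median -0.74, adjusted p = 0.032, and adjusted p = 0.064 with an estimated correlation). The cell cycle list was not called, with 6 of 20 up and 6 down (median 0.04, adjusted p = 0.9), and its median, its mean (-0.11) and the downward test differed in sign. Apart from the endoderm list these counts were the same when adjusted over the list alone. The labels state no medium for either group.

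Male EpiSCs also lost Klf4 and gained Fgf5 (EpiSCm against ESCm, 2 arrays each). Fgf5 was at least 32.5-fold higher (log2 5.64, SE 0.19), the interferon-induced GTPase Gbp2 at least 39.6-fold higher (6.13, SE 0.14) and Chst1 at least 42.7-fold higher (5.98, SE 0.18). Otx2, a homeobox regulator of the primed epiblast, increased 49.3-fold (log2 5.62, SE 0.18) and the carbonic anhydrase Car14 35.4-fold (5.15, SE 0.18). The goosecoid gene Gsc, a mark of the organizer, increased 9.16-fold and the kinase gene Pim2 at least 12.6-fold. Klf4 was 45.2-fold lower (log2 -5.50, SE 0.20), Esrrb 30.1-fold lower (-4.91, SE 0.16), Dppa5a 59.4-fold lower (-5.89, SE 0.17) and Dnmt3l 88.4-fold lower (-6.47, SE 0.13). The unstudied 2210409E12Rik was at least 80.4-fold lower, Ooep 128-fold lower, the germ-cell RNA-binding gene Rbmxl2 at least 59.4-fold lower, the ubiquitin-ligase adaptor Klhl13 at least 60.6-fold lower and Rhox5 88.6-fold lower. Gbx2, a homeobox target of STAT3 signalling, was 33.6-fold lower (log2 -5.07, SE 0.21), and Tbx3, a T-box factor that sustains self-renewal, at least 24.1-fold lower (-5.39, SE 0.15). Nanog fell by 2.98 log2 units (SE 0.14), Sox2 by 1.41 (SE 0.13) and Zfp42 by 3.66. Pou5f1 was not called (-0.04, adjusted p = 0.77), while its second probe rose by 1.07 (adjusted p = 2.6e-06) and the second Sox2 probe fell by 5.92. Chac1, a glutathione-degrading stress gene, and the p53 target Phlda3 rose 4.47-fold and 4.19-fold. The respiratory gene Atp5a1 was 23.7-fold and the replication clamp Pcna 21.8-fold lower.

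Limma's test called 6227 genes, 3671 up and 2556 down (2195 and 3479 under median scaling), and 3309 moved at least 2-fold. Naive pluripotency had 0 of 22 up and 21 down (median -3.86, adjusted p = 1.8e-14), germ line 0 of 11 up and 11 down (median -2.17, adjusted p = 2.9e-06), trophoblast 0 of 14 up and 12 down (median -1.08, adjusted p = 2.5e-04) and core pluripotency 1 of 16 up and 11 down (median -1.13, adjusted p = 4.9e-04). The lists of BMP targets, with 1 of 10 up and 8 down (median -1.58, adjusted p = 0.0017), and LIF-STAT3, with 3 of 14 up and 9 down (median -1.50, adjusted p = 0.0047), also fell, as did fibroblast and feeder cells, with 1 of 16 up and 10 down (median -1.32, adjusted p = 0.0047, and adjusted p = 0.1 with an estimated correlation). Primed pluripotency rose with 16 of 21 up and 4 down (median 2.48, adjusted p = 4.9e-04) and p53 and apoptosis with 11 of 16 up and 0 down (median 0.94, adjusted p = 0.011). These counts were the same adjusted over the list alone. EpiSCm lies in the dimmer set of 8 arrays and ESCm in the brighter set of 16, so this comparison cannot be told apart from the array set. Of the genes called in both pairs (4035), 83.6% moved in the same direction (r 0.60 over all genes). Both pairs called 1995 genes up and 1380 down, where 1208 and 698 would be expected by independence.

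The EpiSC minus ESC difference was not the same in the female and male pairs. Npy (log2 difference 7.61, SE 0.19), Gbx2 (6.50, SE 0.29), the mitochondrial gene Fastkd3 (5.34, SE 0.34), the Wnt antagonist Sfrp2 (4.71, SE 0.37) and the vesicle protein Vapa (4.58, SE 0.20) were higher on the female side. Xlr4a (-6.61, SE 0.19), Gbp2 (-6.11, SE 0.20), Gm14685 (-5.12, SE 0.32), the RNA-modification gene Thumpd1 (-4.82, SE 0.17) and Fmr1nb (-4.69, SE 0.25) were higher on the male side. The test called 4525 genes, 2058 up and 2467 down (3704 and 1048 under median scaling). Sex, strain of origin and array set changed together here.

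In F9 cells, which hold many naive transcripts, placental homeobox genes rose with Sox2 (F9-Sox2 against F9 EC, 2 arrays each). Rhox6 increased at least 19.9-fold (log2 4.98, SE 0.18) and Rhox9 24.9-fold (4.64, SE 0.20), both of the X-linked reproductive homeobox cluster. The iron exporter Slc40a1 increased at least 11.6-fold (log2 4.35, SE 0.16), the germ-line and naive marker Dppa3 11.3-fold (3.50, SE 0.22) and the RNA-binding gene Igf2bp3 6.74-fold (2.75, SE 0.13). Tfap2c rose 3.23-fold, Otx2 3-fold, the splicing regulator of epithelia Esrp1 4.21-fold and the immediate-early gene Egr1 3.36-fold. Bhlhe40, a clock-linked repressor, was 15.3-fold lower (log2 -3.94, SE 0.19), the matrix protein Tgfbi 8.48-fold lower (-3.08, SE 0.15) and the cell-surface gene Igsf21 at least 2.70-fold lower (-2.49, SE 0.24). Bahcc1, a chromatin reader, was 4.42-fold and the lipolysis inhibitor G0s2 4.05-fold lower (log2 -2.14 and -2.02). Ndrg1, a hypoxia-induced gene, was 3.46-fold, Mras 3-fold, Sox7 2.74-fold and the cell-cycle inhibitor Cdkn1c 2.32-fold lower. Sox15 rose 2.60-fold. Pou5f1 (log2 -0.16), Nanog (0.09), Klf4 (0.29), Esrrb (-0.28) and Zfp42 (0.15) were not called, with SE 0.13 to 0.20. Fgf5 lay near background and fell by 0.67 (adjusted p = 0.037). Lefty2 rose and its paralog Lefty1, both inhibitors of Nodal, fell (log2 1.14 and -0.97).

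Calls numbered 868, 479 up and 389 down (374 and 568 under median scaling), of which 256 moved at least 2-fold. The count was 469 without the second F9 EC array and at most 505 without any other array of the pair. By list, trophoblast had 6 of 14 up and 0 down, or 7 and 0 adjusted over the list alone (median 0.37, adjusted p = 1.2e-05). Glycolysis and hypoxia had 0 of 22 up and 5 down, or 1 and 8 adjusted over the list alone (median -0.30, adjusted p = 0.0071, and adjusted p = 0.19 with an estimated correlation), and germ line 3 of 11 up and 0 down (median 0.13, adjusted p = 0.04, and adjusted p = 0.13 with an estimated correlation), with the same count adjusted over the list alone.

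In P19 carcinoma cells, which hold few naive transcripts, the largest rises were other genes (P19-Sox2 against P19 EC, 2 arrays each). Acta2 increased 18.2-fold (log2 4.19, SE 0.15), the actin-associated Fam107a at least 5.78-fold (3.78, SE 0.15) and the T-cell adaptor Lat at least 8.75-fold (3.55, SE 0.19). Sox21, a neural Sox gene and known Sox2 target, increased at least 6.96-fold (log2 3.54, SE 0.26) and the protease inhibitor Timp4 9.25-fold (3.21, SE 0.18). Fgf5 rose 3.96-fold (log2 1.99, SE 0.19), Nanog 1.70-fold (0.76, SE 0.14) and Tcf7l1, a repressor of naive genes, 2.97-fold. Gadd45a, a DNA-damage gene, rose 3.15-fold, the Wnt receptor Fzd7 2.95-fold, the imprinted growth factor Igf2 2.62-fold and the surface antigen Thy1 3.76-fold. Gbp2 was at least 9.85-fold lower (log2 -4.26, SE 0.14) and Oasl2, another interferon-induced gene, at least 4.57-fold lower (-3.19, SE 0.16). The caudal homeobox gene Cdx2 was at least 4.24-fold lower (log2 -2.92, SE 0.14), the arginase Arg1 at least 3.31-fold lower (-2.77, SE 0.18) and the streak ligand Wnt8a at least 3.08-fold lower (-2.47, SE 0.16). Sp5, a Wnt target, was at least 2.50-fold, Nodal 2.93-fold, Lefty1 2.47-fold, the streak gene Evx1 at least 2.54-fold and Fgf8 2.31-fold lower. Klf4 (log2 -0.14), Esrrb (-0.23), Zfp42 (-0.12) and Pou5f1 (-0.13) were not called.

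The test called 929 genes, 526 up and 403 down (361 and 546 under median scaling), with 229 at least 2-fold. Without the first P19 EC array 522 were called, without the second 480, without the second P19-Sox2 array 519 and over only these groups 574. Among the lists, neural and ectoderm had 3 of 9 up and 1 down, or 4 and 1 adjusted over the list alone (median 0.56, adjusted p = 0.023, and adjusted p = 0.062 with an estimated correlation). Epithelial and mesenchymal had 8 of 15 up and 3 down (median 0.68, adjusted p = 0.023, and adjusted p = 0.062 with an estimated correlation), the same count as adjusted over the list alone. Nodal-Activin had 1 of 12 up and 3 down, or 2 and 4 adjusted over the list alone (median -0.32, adjusted p = 0.023, and adjusted p = 0.062 with an estimated correlation).

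In the arrays labelled Epi-Sox2f the largest rises over EpiSCf were those of Anxa2, Acta2 and Myl1 (2 arrays each). Anxa2, a membrane-binding annexin, increased 16.5-fold (log2 4.05, SE 0.16), Acta2 at least 11.4-fold (3.97, SE 0.15) and the myosin light chain Myl1 at least 3.80-fold (3.04, SE 0.14). Tgfbi increased 8.14-fold (log2 3.02, SE 0.15), opposite to its fall in F9-Sox2, and the annexin Anxa3 7.18-fold (2.84, SE 0.17). The glycolytic aldolase Aldoc rose 3.64-fold, the oxygen sensor Egln3 3.26-fold, the stress gene Ddit4 3-fold, the matrix protein Sparc 3.17-fold and the mesenchymal filament gene Vim 2.77-fold. The translation repressor Eif4ebp2 was 4.18-fold lower (log2 -2.06, SE 0.28), the histone methyltransferase Ehmt1 3.86-fold lower (-1.95, SE 0.13) and the VEGF receptor Flt1 3.78-fold lower (-1.92, SE 0.23). Zscan10, a pluripotency zinc-finger gene, was 3.63-fold lower (log2 -1.86, SE 0.20) and the kinase gene Sgk1 3.61-fold lower (-1.85, SE 0.20). Axin2, a Wnt target, was 2.60-fold, Furin 2.40-fold, Tcf7l1 2.21-fold and the epiblast gene Utf1 2.03-fold lower. Pou5f1 rose by 0.55 log2 units (SE 0.13), Sox21 by 1.10, and the naive genes Gbx2 by 0.87, Klf5 by 0.43 and, from background, Esrrb by 0.53. Nanog (0.30), Klf4 (0.33), Zfp42 (-0.04) and Fgf5 (0.31) were not called.

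The calls comprised 2577 genes, 1207 up and 1370 down (826 and 1424 under median scaling), of which 434 moved at least 2-fold. Without the first EpiSCf array 1493 were called, and without the first or the second Epi-Sox2f array 1516 or 1716. Glycolysis and hypoxia had 11 of 22 up and 1 down (median 0.40, adjusted p = 6.5e-04, and adjusted p = 0.14 with an estimated correlation), the same count as adjusted over the list alone. Neural and ectoderm had 5 of 9 up and 0 down, or 6 and 0 adjusted over the list alone (median 0.57, adjusted p = 0.0054, and adjusted p = 0.08 with an estimated correlation). As neither Sox2 probe rose, no change here can be assigned to the transgene.

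In male EpiSCs kept in EpiSC medium, Sox2 was accompanied by a gain of naive and germ-line genes and a loss of streak genes (EpiSox2mL2 against EpiSCm, 2 arrays each). Rbmxl2 increased at least 19-fold (log2 4.89, SE 0.14), Dppa5a 21.8-fold (4.45, SE 0.17) and the membrane protein Vstm2l 14.2-fold (3.83, SE 0.18). The X-linked testis gene Tex13b increased at least 8.92-fold (log2 3.77, SE 0.13) and Dppa4 12.9-fold (3.69, SE 0.12). Esrrb rose 10.8-fold (log2 3.43, SE 0.16), Dnmt3l 10.5-fold (3.40, SE 0.13), Gbx2 9.53-fold (3.25, SE 0.21) and Zfp42 7.36-fold (2.88, SE 0.19). Rhox5 rose 8.53-fold, Tfap2c 3.58-fold, Tex19.1 5.07-fold, Dppa3 4.83-fold, Acta2 5.46-fold and Lefty2 4.87-fold. Fgf8 was 12.1-fold lower (log2 -3.59, SE 0.20), Gsc at least 9.42-fold lower (-3.48, SE 0.20) and the organizer gene Lhx1 at least 3.64-fold lower (-2.69, SE 0.17). Fgf5 was 5.69-fold lower (log2 -2.51, SE 0.19) and the thioesterase Them5 4.91-fold lower (-2.30, SE 0.25). Fgf4, a Sox2 and Oct4 target, rose 3.90-fold, the ERK phosphatase Dusp4 3.15-fold and the stress factor Ddit3 3.23-fold. Nanog (log2 -0.10), Klf4 (0.23) and Pou5f1 (-0.14) were not called, but the other 2 Klf4 probes rose by 1.15 and 0.87 (adjusted p = 7.2e-04 and 0.030).

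Limma's test called 2167 genes, 1153 up and 1014 down (608 and 906 under median scaling), of which 381 moved at least 2-fold. Without the first EpiSox2mL2 array 1154 were called, without the second 1398, over only the dimmer arrays 1229 and over only these groups 676. Naive pluripotency had 16 of 22 up and 0 down (median 1.39, adjusted p = 1.3e-17), p53 and apoptosis 9 of 16 up and 0 down (median 0.59, adjusted p = 3.7e-05) and germ line 5 of 11 up and 0 down (median 0.32, adjusted p = 0.0018), the same counts as adjusted over the list alone. LIF-STAT3 had 6 of 14 up and 0 down, or 7 and 0 adjusted over the list alone (median 0.42, adjusted p = 1.4e-04) and mesendoderm 0 of 16 up and 8 down (median -0.44, adjusted p = 1.5e-04). Trophoblast had 5 of 14 up and 1 down (median 0.30, adjusted p = 0.016, and adjusted p = 0.08 with an estimated correlation), unchanged like mesendoderm when adjusted over the list alone. DNA methylation had 4 of 10 up and 0 down, or 5 and 1 adjusted over the list alone (median 0.36, adjusted p = 0.0094, and adjusted p = 0.059 with an estimated correlation), and FGF-ERK targets 6 of 17 up and 0 down, or 7 and 0 adjusted over the list alone (median 0.24, adjusted p = 0.01, and adjusted p = 0.08 with an estimated correlation).

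The Sox2 line in ESC medium gained another mixture, with streak and Wnt genes rising beside part of the naive set (EpiSox2mE1 against EpiSCm, 2 arrays each). Dnmt3l increased 31.4-fold (log2 4.97, SE 0.13), Dppa5a 23.1-fold (4.53, SE 0.17) and Sp5 16-fold. Fst, an activin-binding protein, increased 14.6-fold (log2 3.86, SE 0.26), and the homeobox gene En1, a Wnt target in the embryo, at least 8.79-fold (3.86, SE 0.18). Klf2, a naive Kruppel factor, rose 9.47-fold (log2 3.24, SE 0.15), Dppa4 6.92-fold, Gbx2 5.15-fold, Esrrb 2.31-fold (1.21, SE 0.16) and Nanog 1.84-fold (0.88, SE 0.14). Of the streak genes, the repressor Snai1 rose at least 6.04-fold, Evx1 5.02-fold, Cdx2 at least 2.33-fold and the homeobox gene Mixl1 4.21-fold. Axin2 rose 4.40-fold, Msx1, a BMP target, 6.31-fold, and the pyruvate dehydrogenase kinase Pdk1 3.47-fold. The complement inhibitors Cd59a and Cd59b were 41-fold lower and at least 5.55-fold lower (log2 -5.36, SE 0.15 and -3.22, SE 0.20). Car4 was 16.4-fold lower (log2 -4.04, SE 0.14), Chst1 12.6-fold lower (-3.66, SE 0.18) and the tetraspanin Tspan6 11-fold lower (-3.46, SE 0.19). The neural filament gene Nes was 3.51-fold, the keratin Krt18 3.65-fold and Xlr4a at least 2.53-fold lower. Zfp42 fell by 0.74 (adjusted p = 0.0071), and Klf4 (-0.32), Pou5f1 (0.08) and Fgf5 (0.12) were not called.

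Limma's test called 2565 genes, 1179 up and 1386 down (601 and 1236 under median scaling), or 1313 over only these groups, with 689 at least 2-fold. Glycolysis and hypoxia had 11 of 22 up and 1 down, or 15 and 1 adjusted over the list alone (median 0.43, adjusted p = 5.0e-05), mesendoderm 9 of 16 up and 2 down, or 9 and 3 adjusted over the list alone (median 1.13, adjusted p = 2.3e-04) and fibroblast and feeder cells 8 of 16 up and 3 down, or 11 and 3 adjusted over the list alone (median 0.61, adjusted p = 0.0014). Naive pluripotency had 9 of 22 up and 1 down (median 0.10, adjusted p = 2.3e-04), Wnt targets 5 of 13 up and 0 down (median 0.30, adjusted p = 5.1e-04), FGF-ERK targets 9 of 17 up and 1 down (median 0.55, adjusted p = 6.4e-04), BMP targets 4 of 10 up and 0 down (median 0.52, adjusted p = 0.0031) and LIF-STAT3 8 of 14 up and 1 down (median 0.64, adjusted p = 0.0037). Trophoblast had 4 of 14 up and 1 down (median 0.30, adjusted p = 0.0031), DNA methylation 4 of 10 up and 0 down (median 0.25, adjusted p = 0.006) and core pluripotency 7 of 16 up and 1 down (median 0.19, adjusted p = 0.006), and these 8 counts were the same adjusted over the list alone. The p53 and apoptosis list fell, with 0 of 16 up and 8 down, or 1 and 10 adjusted over the list alone (median -0.46, adjusted p = 0.0037). Neural and ectoderm had 0 of 9 up and 5 down, or 2 and 5 adjusted over the list alone (median -0.96, adjusted p = 0.0499, and adjusted p = 0.075 with an estimated correlation). EpiSox2mE1 differs from EpiSCm in both transgene and medium, so the effect of either alone cannot be read from it.

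The second ESC-medium group shared the leading rises of Dnmt3l and Dppa5a (EpiSox2mE2 against EpiSCm, 2 arrays each). Dnmt3l increased 32.3-fold (log2 5.02, SE 0.13), Dppa5a 26.8-fold (4.74, SE 0.17) and the matrix proteoglycan Bgn at least 10.5-fold (4.20, SE 0.22). En1 rose at least 10.8-fold (log2 4.16, SE 0.18), Sp5 16.5-fold (4.04, SE 0.15), Fst 12.3-fold and Klf2 11.1-fold. Snai1 increased at least 8.08-fold (log2 3.26, SE 0.28), Evx1 5.76-fold, Mixl1 4.86-fold and the endoderm factor Foxa2 4.51-fold. Gbx2 rose 8.41-fold, Dppa4 13.9-fold, Esrrb 3.48-fold, Nanog 1.82-fold and, unlike in EpiSox2mE1, Zfp42 1.96-fold (log2 0.97, SE 0.19). Lox, a collagen crosslinker, and the matrix gene Fbln2 rose at least 4.36-fold and 7.28-fold. Cd59a was 52.8-fold lower (log2 -5.72, SE 0.15), the pregnancy glycoprotein Psg23 14.7-fold lower (-3.87, SE 0.37) and Tspan6 11.5-fold lower (-3.52, SE 0.19). The peroxisome gene Pex2 was 10.4-fold lower (log2 -3.37, SE 0.15), Cd59b at least 5.58-fold lower (-3.29, SE 0.20), Car4 6.49-fold lower and the imprinted neuronatin gene Nnat at least 5.06-fold lower. Klf4 (log2 -0.31), Fgf5 (0.34) and Pou5f1 (-0.03) were not called, but a second Klf4 probe rose by 1.19 (adjusted p = 3.6e-04).

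The test called 2535 genes, 1104 up and 1431 down (328 and 2400 under median scaling), or 802 over only these groups, with 673 at least 2-fold. Naive pluripotency had 12 of 22 up and 0 down (median 0.79, adjusted p = 8.9e-09), mesendoderm 9 of 16 up and 2 down (median 1.00, adjusted p = 9.8e-05), Wnt targets 5 of 13 up and 0 down (median 0.51, adjusted p = 0.0012), BMP targets 5 of 10 up and 0 down (median 0.47, adjusted p = 0.012) and DNA methylation 4 of 10 up and 1 down (median 0.20, adjusted p = 0.0057), the same counts as adjusted over the list alone. Fibroblast and feeder cells had 9 of 16 up and 1 down, or 10 and 1 adjusted over the list alone (median 0.72, adjusted p = 9.7e-05), glycolysis and hypoxia 12 of 22 up and 1 down, or 14 and 1 adjusted over the list alone (median 0.53, adjusted p = 1.5e-04) and FGF-ERK targets 7 of 17 up and 0 down, or 8 and 1 adjusted over the list alone (median 0.35, adjusted p = 2.1e-04). Core pluripotency had 6 of 16 up and 0 down, or 6 and 1 adjusted over the list alone (median 0.31, adjusted p = 0.0012) and trophoblast 5 of 14 up and 0 down, or 5 and 1 adjusted over the list alone (median 0.35, adjusted p = 0.0037). LIF-STAT3 had 5 of 14 up and 2 down (median 0.35, adjusted p = 0.032, and adjusted p = 0.051 with an estimated correlation). The X-linked silencing and Y-linked list had 1 of 5 up and 0 down (median 0.32, adjusted p = 0.035, and adjusted p = 0.12 with an estimated correlation), and for these last lists the counts were the same adjusted over the list alone.

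Set directly against each other, the ESC-medium lines differed in few genes (EpiSox2mE2 against EpiSox2mE1, 2 arrays each). Rbmxl2 (log2 2.97, SE 0.14), Usp9y (2.90, SE 0.13), Tex13b (2.77, SE 0.13), the phospholipase Pla2g1b (2.33, SE 0.17) and the peptidase Dpp4 (2.18, SE 0.23) were higher in EpiSox2mE2. Vstm2l (-3.69, SE 0.18), the coactivator Cited1 (-2.54, SE 0.18), the lactate dehydrogenase Ldhd (-1.99, SE 0.16), Id2 (-1.62, SE 0.20), an inhibitor of differentiation, and the lipid lyase Sgpl1 (-1.39, SE 0.22) were lower. Zfp42 was 3.27-fold, Tex19.1 3.18-fold, Car4 2.53-fold, Dppa4 2-fold, Rhox5 2.20-fold and the receptor gene Nr5a2 at least 1.14-fold higher. Nnat was at least 1.62-fold and the keratin Krt19 2.34-fold lower. Sox2 (0.12), Pou5f1 (-0.11), Nanog (-0.02), Klf4 (0.01), Esrrb (0.59) and Fgf5 (0.22) were not called, but a second Klf4 probe was higher in EpiSox2mE2 by 1.51 (adjusted p = 4.1e-04). The test called 213 genes, 100 up and 113 down (18 and 136 under median scaling), with 60 at least 2-fold, and 99 were called without the second EpiSox2mE1 array, 33 over only the dimmer arrays and 10 over only these groups. The X-linked silencing and Y-linked list had 2 of 5 up and 0 down (median 0.65, adjusted p = 3.0e-05), naive pluripotency 4 of 22 up and 1 down, or 6 and 1 adjusted over the list alone (median 0.19, adjusted p = 4.6e-04) and germ line 2 of 11 up and 0 down, or 3 and 0 adjusted over the list alone (median 0.25, adjusted p = 5.7e-04). Primed pluripotency had 2 of 21 up and 0 down (median 0.19, adjusted p = 0.0043, and adjusted p = 0.11 with an estimated correlation), and its count and the first of these were the same adjusted over the list alone. Of 1836 genes called in both against EpiSCm, 99.6% moved in the same direction.

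The largest rises of EpiSox2mE1 in ESC medium over EpiSox2mL2 in EpiSC medium included streak genes (2 arrays each). Fgf8 was 37.8-fold higher in EpiSox2mE1 (log2 5.24, SE 0.20), Gsc at least 26.4-fold higher (4.96, SE 0.20) and Sp5 26.8-fold higher (4.74, SE 0.15). En1 was at least 9.19-fold higher (log2 4.05, SE 0.18), the leukocyte protease inhibitor Slpi 13.8-fold higher (3.79, SE 0.15) and Fst 12.9-fold higher. Mixl1 was at least 5.43-fold, Foxa2 at least 3.29-fold, Fgf5 6.18-fold (log2 2.63, SE 0.19), Msx1 8.32-fold and Nanog 1.98-fold higher (0.98, SE 0.14). Ndrg1 was 8.54-fold, Egln3 4.57-fold and Pdk1 3.11-fold higher. Txnip, a glucose-responsive thioredoxin inhibitor, was at least 24.1-fold lower (log2 -5.05, SE 0.27), Rbmxl2 at least 17.5-fold lower (-4.89, SE 0.14) and Cd59a 20.8-fold lower (-4.38, SE 0.15). The detoxifying transferase Gstp2 was at least 11.6-fold lower (log2 -4.23, SE 0.19), the complement-like C1ql2 at least 12.1-fold lower (-4.08, SE 0.15) and Zfp42 12.3-fold lower (-3.62, SE 0.19). Esrrb fell by 2.22 (SE 0.16), Klf4, near background in both, by 0.55 (adjusted p = 0.045) and the tight-junction gene Cldn4 by 3.05. Tex19.1 was 7.98-fold, Rhox5 6.79-fold and the stress genes Chac1 and Trp53inp1 3.60-fold and 3.16-fold lower. Sox2 (0.25) and Pou5f1 (0.22) were not called, but the second Pou5f1 probe rose by 0.45 (adjusted p = 0.024).

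There were 2787 called genes, 1248 up and 1539 down, with 793 at least 2-fold. Mesendoderm had 11 of 16 up and 0 down, or 11 and 1 adjusted over the list alone (median 1.81, adjusted p = 5.2e-10), glycolysis and hypoxia 15 of 22 up and 1 down, or 15 and 2 adjusted over the list alone (median 0.87, adjusted p = 1.4e-06) and Wnt targets 6 of 13 up and 1 down, or 6 and 2 adjusted over the list alone (median 0.47, adjusted p = 0.0014). The p53 and apoptosis list fell with 0 of 16 up and 15 down, or 0 and 16 adjusted over the list alone (median -1.02, adjusted p = 7.0e-09), naive pluripotency with 3 of 22 up and 11 down, or 3 and 12 adjusted over the list alone (median -0.45, adjusted p = 0.0037), germ line with 0 of 11 up and 5 down, or 0 and 6 adjusted over the list alone (median -0.76, adjusted p = 0.0054) and epithelial and mesenchymal with 2 of 15 up and 6 down, or 2 and 7 adjusted over the list alone (median -0.39, adjusted p = 0.021). Extraembryonic endoderm had 1 of 15 up and 7 down (median -0.41, adjusted p = 0.023, and adjusted p = 0.084 with an estimated correlation). The X-linked silencing and Y-linked list had 0 of 5 up and 3 down (median -0.66, adjusted p = 0.033, and adjusted p = 0.13 with an estimated correlation), and these last counts stayed the same adjusted over the list alone.

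Fgf8, Gsc and Sp5 also led EpiSox2mE2 against EpiSox2mL2 (2 arrays each). Fgf8 was 30.5-fold higher (log2 4.93, SE 0.20), Sp5 27.7-fold higher (4.79, SE 0.15), Gsc at least 20.7-fold higher (4.61, SE 0.20), En1 at least 11.3-fold higher (4.35, SE 0.18) and Fst 10.8-fold higher (3.44, SE 0.26). Mixl1 was at least 6.26-fold, Foxa2 at least 4.47-fold, Snai1 7.46-fold, Fgf5 7.18-fold and Msx1 7.13-fold higher. Nanog was 1.96-fold higher (log2 0.97, SE 0.14) and Sox2 1.29-fold higher (0.37, SE 0.13, adjusted p = 0.033). Txnip was at least 24.2-fold lower (log2 -5.21, SE 0.27), Cd59a 26.8-fold lower (-4.74, SE 0.15), Vstm2l 22.4-fold lower (-4.48, SE 0.18) and C1ql2 at least 12.1-fold lower (-3.86, SE 0.15). Got1l1, an aspartate-metabolism gene, was at least 9.98-fold (log2 -3.90, SE 0.25), Zfp42 3.76-fold, Esrrb 3.09-fold, Cldn4 7.95-fold and Lefty2 5.35-fold lower. Klf4 fell by 0.54 (adjusted p = 0.043), Chac1 by 1.93 and Id2 by 1.96, while Pou5f1 (0.11), the other 2 Klf4 probes (0.04 and -0.34) and the second Sox2 probe (0.13, adjusted p = 0.56) were not called.

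The test called 3139 genes, 1399 up and 1740 down (392 and 2040 under median scaling), or 1690 over only these groups, with 872 at least 2-fold. Mesendoderm had 11 of 16 up and 0 down, or 11 and 1 adjusted over the list alone (median 1.85, adjusted p = 1.3e-09) and the p53 and apoptosis list 0 of 16 up and 13 down, or 0 and 15 adjusted over the list alone (median -0.82, adjusted p = 1.5e-06). Glycolysis and hypoxia had 14 of 22 up and 2 down (median 0.70, adjusted p = 3.4e-05) and Wnt targets 7 of 13 up and 1 down (median 0.57, adjusted p = 0.0085), the same counts as adjusted over the list alone. Fibroblast and feeder cells had 8 of 16 up and 3 down, or 9 and 3 adjusted over the list alone (median 0.61, adjusted p = 0.021, and adjusted p = 0.15 with an estimated correlation). Extraembryonic endoderm had 1 of 15 up and 7 down (median -0.35, adjusted p = 0.035, and adjusted p = 0.11 with an estimated correlation), unchanged when adjusted over the list alone. Oxidative phosphorylation had 0 of 23 up and 10 down, or 2 and 10 adjusted over the list alone (median -0.27, adjusted p = 0.035, and adjusted p = 0.18 with an estimated correlation). Lists called for EpiSox2mE1 but not here included naive pluripotency, with 3 of 22 up and 8 down (median -0.28, adjusted p = 0.13) and the same count adjusted over the list alone, germ line (adjusted p = 0.12) and epithelial and mesenchymal (adjusted p = 0.056). Medium and line vary together among these 3 groups.

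**Figure D2:**
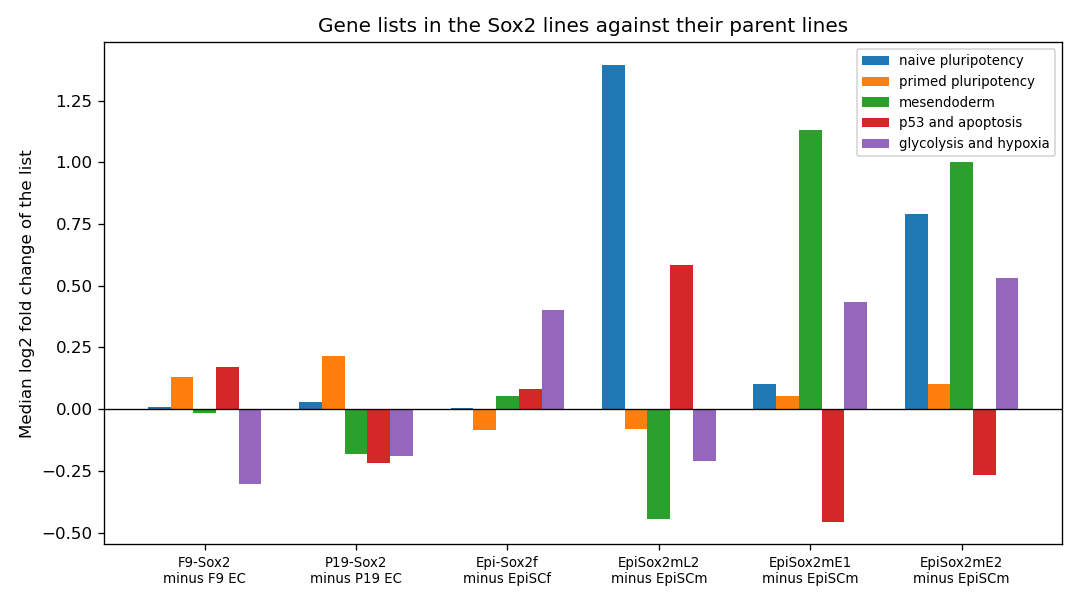
Median log2 fold change of 5 gene lists in each Sox2 group against its parent line. The naive pluripotency median was 1.39 in EpiSox2mL2, and the mesendoderm medians were 1.13 and 1.00 in EpiSox2mE1 and EpiSox2mE2.

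Neither ESC-medium line matched male ES cells (EpiSox2mE1 against ESCm, 2 arrays each). Vstm2l was at least 79.7-fold higher (log2 6.99, SE 0.18), Fst at least 83.8-fold higher (6.79, SE 0.26), Fgf8 at least 66.9-fold higher (6.43, SE 0.20), Gbp2 at least 45.4-fold higher (6.33, SE 0.14) and Slpi at least 29.3-fold higher. Fgf5 was at least 35.3-fold, Otx2 48.6-fold and Gsc 25.6-fold higher (log2 5.76, 5.60 and 4.68). Sp5 was 8.86-fold, Axin2 5.13-fold and Mixl1 at least 4.76-fold higher. On the lower side lay 2210409E12Rik (at least 74.1-fold, log2 -7.17, SE 0.20), Klhl13 (at least 55.9-fold, -6.71, SE 0.18), Rbmxl2 (at least 54.7-fold, -6.54, SE 0.14), Ooep (91.2-fold, -6.51, SE 0.12) and Rhox5 (70.5-fold, -6.14, SE 0.18). Klf4 was at least 38.9-fold (log2 -5.81, SE 0.20), Zfp42 21.2-fold, Esrrb 13-fold and Nanog 4.29-fold lower. The adhesion gene Jam2 was at least 32.2-fold, the AKT coactivator Tcl1 at least 23.8-fold, Tbx3 21.4-fold and the RNA-binding Lin28a 13.3-fold lower. Atp5a1 and Pcna were 20.6-fold and 38.6-fold lower. Other Klf4 probes fell by 4.55 and 3.12. Sox2 (-0.23, adjusted p = 0.12) and Pou5f1 (0.04) were not called, while the second Sox2 probe fell by 5.18 and the second Pou5f1 probe rose by 1.22 (adjusted p = 1.3e-14 and 5.6e-07).

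In all 6007 genes were called, 3492 up and 2515 down (1719 and 3705 under median scaling), with 3059 at least 2-fold. Naive pluripotency had 0 of 22 up and 21 down (median -2.60, adjusted p = 3.7e-12), germ line 0 of 11 up and 11 down (median -2.59, adjusted p = 7.1e-07), core pluripotency 2 of 16 up and 10 down (median -0.61, adjusted p = 0.0097) and mesendoderm 10 of 16 up and 1 down (median 1.56, adjusted p = 0.0097). Primed pluripotency had 14 of 21 up and 3 down (median 1.52, adjusted p = 0.0036, and adjusted p = 0.058 with an estimated correlation). BMP targets had 2 of 10 up and 8 down (median -1.46, adjusted p = 0.021, and adjusted p = 0.058 with an estimated correlation), and trophoblast 2 of 14 up and 9 down (median -0.62, adjusted p = 0.04, and adjusted p = 0.11 with an estimated correlation). Adjusted over the list alone, none of these counts changed. The array set differs between these groups, as it does for the next comparison.

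EpiSox2mE2 against ESCm (2 arrays each) led with Gbp2 (at least 54.3-fold, log2 6.59, SE 0.14), Fst (at least 70.5-fold, 6.54, SE 0.26), Fgf8 (at least 53.9-fold, 6.12, SE 0.20), Fgf5 (at least 41.1-fold, 5.98, SE 0.19) and Otx2 (50.8-fold, 5.67, SE 0.18) on the higher side. Gsc was 20.1-fold, Mixl1 at least 5.49-fold, Sp5 9.15-fold and Pim2 at least 14.2-fold higher. Lower were 2210409E12Rik (at least 74.6-fold, log2 -6.94, SE 0.20), Klhl13 (at least 56.2-fold, -6.62, SE 0.18), the sorting nexin Snx5 (at least 43.3-fold, -5.92, SE 0.24), the tubulin regulator Stmn1 (58.2-fold, -5.86, SE 0.24) and Klf4 (at least 39.2-fold, -5.81, SE 0.20). Jam2 was at least 32.4-fold, Tbx3 at least 22.3-fold, Tcl1 at least 23.9-fold, Esrrb 8.64-fold, Zfp42 6.47-fold and Nanog 4.34-fold lower. The amino-acid transporter Slc38a4, imprinted in the mouse, was at least 17.9-fold lower, and the coreceptor of Nodal Tdgf1 11.7-fold lower. Sox2 (-0.11, adjusted p = 0.45) and Pou5f1 (-0.07) were not called, while the second Sox2 probe fell by 4.97 and the second Pou5f1 probe rose by 0.97 (adjusted p = 3.0e-14 and 9.2e-06).

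The test called 5860 genes, 3361 up and 2499 down (1185 and 4429 under median scaling), with 2971 at least 2-fold. Naive pluripotency had 0 of 22 up and 21 down (median -2.26, adjusted p = 3.8e-11), germ line 0 of 11 up and 11 down (median -2.22, adjusted p = 4.4e-06), primed pluripotency 14 of 21 up and 1 down (median 2.22, adjusted p = 7.3e-05) and mesendoderm 9 of 16 up and 1 down (median 1.90, adjusted p = 0.0087). Trophoblast had 1 of 14 up and 9 down (median -0.69, adjusted p = 0.022, and adjusted p = 0.065 with an estimated correlation). LIF-STAT3 had 3 of 14 up and 8 down (median -1.11, adjusted p = 0.023, and adjusted p = 0.052 with an estimated correlation), and core pluripotency 3 of 16 up and 9 down (median -0.71, adjusted p = 0.023, and adjusted p = 0.052 with an estimated correlation). BMP targets had 2 of 10 up and 7 down (median -1.13, adjusted p = 0.025, and adjusted p = 0.06 with an estimated correlation), and oxidative phosphorylation 5 of 23 up and 11 down (median -0.27, adjusted p = 0.029, and adjusted p = 0.18 with an estimated correlation). Each of these counts was the same adjusted over the list alone.

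Naive transcripts were lower in the P19 than in the F9 parental line (P19 EC against F9 EC, 2 arrays each). The neural zinc-finger gene Zic1 was at least 39.1-fold higher in P19 EC (log2 6.58, SE 0.14), Npy at least 38.3-fold higher (6.49, SE 0.13) and the ubiquitin ligase Pdzrn3 at least 36-fold higher (6.24, SE 0.14). The LIM-binding Ldb2 was at least 17.4-fold higher (log2 5.46, SE 0.13) and Otx2 43.5-fold higher (5.44, SE 0.18). Fgf8 was at least 5.26-fold higher, Pim2 at least 10.3-fold higher, Fgf15 at least 6.07-fold higher, the imprinted placental gene Phlda2 23.5-fold higher and the mitotic kinase Plk1 25-fold higher. Tcl1 was at least 88.8-fold lower (log2 -7.59, SE 0.12), Esrrb 180-fold lower (-7.49, SE 0.16), the lysosomal gene Laptm5 at least 77.1-fold lower (-7.42, SE 0.13), Rbmxl2 at least 39-fold lower (-6.53, SE 0.14) and Sox21 at least 49.3-fold lower (-6.37, SE 0.26). Zfp42 was 79.4-fold, Gbx2 64.4-fold, Bmp4 33.3-fold, Klf4 7.61-fold and Nanog 6.92-fold lower (log2 -6.31, -6.01, -5.06, -2.93 and -2.79). Pou5f1 rose by 1.04 (SE 0.13), Fgf5 by 2.01, and Sox2 fell by 0.54 (SE 0.13). Eif2s3y was at least 12.1-fold higher.

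Altogether 4920 genes were called, 2504 up and 2416 down, with 2211 at least 2-fold. Naive pluripotency had 1 of 22 up and 16 down (median -3.34, adjusted p = 1.7e-10), imprinted 11 of 17 up and 2 down (median 1.01, adjusted p = 0.0079) and LIF-STAT3 0 of 14 up and 11 down, or 1 and 11 adjusted over the list alone (median -1.51, adjusted p = 9.3e-05). Primed pluripotency had 12 of 21 up and 2 down (median 0.64, adjusted p = 0.0035, and adjusted p = 0.086 with an estimated correlation). Fibroblast and feeder cells had 9 of 16 up and 2 down (median 1.07, adjusted p = 0.018, and adjusted p = 0.19 with an estimated correlation), and the Sox family 0 of 9 up and 4 down (median -0.43, adjusted p = 0.044, and adjusted p = 0.1 with an estimated correlation). Adjusted over the list alone, the counts other than that of LIF-STAT3 were the same. Of 3278 genes called both here and in the female EpiSC pair, 62.6% moved in the same direction (r 0.32), with 1134 up and 917 down in both against 824 and 660 expected.

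The change from parent to Sox2 line differed between the lines. It cannot be assigned to Sox2 in Epi-Sox2f, or told apart from other line differences elsewhere. Between F9 and P19 it differed for 892 genes, led by Rhox6 (log2 4.88, SE 0.25), Rhox9 (4.52, SE 0.28), Gbp2 (4.30, SE 0.20), Slc40a1 (4.16, SE 0.23) and the interferon-induced Ifitm3 (4.04, SE 0.19) on the F9 side. Acta2 (-4.06, SE 0.22), Bhlhe40 (-3.99, SE 0.26), Lat (-3.73, SE 0.27), Fam107a (-3.70, SE 0.21) and Tgfbi (-3.17, SE 0.21) led on the P19 side. Against the arrays labelled Epi-Sox2f, F9 differed for 1956 genes, with Rhox6 (5.02), Rhox9 (4.53), Slc40a1 (3.89), Zfp608 (3.76) and Dppa3 (3.56) above and Tgfbi (-6.11), Bhlhe40 (-5.73), Acta2 (-3.85), Anxa2 (-3.55) and the phosphoglucomutase Pgm1 (-2.95) below. Against EpiSox2mL2 it differed for 1476 genes, with Rhox6 (4.57), the trypsin inhibitor Spink1 (4.23), Slc40a1 (3.86), Gsc (3.81) and Fgf8 (3.49) above and Rbmxl2 (-4.84), Dppa5a (-4.71), Bhlhe40 (-4.58), Vstm2l (-4.57) and Tgfbi (-4.00) below.

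For P19 the difference from the arrays labelled Epi-Sox2f held 1734 genes, but 1118 without the first EpiSCf array. Fam107a (3.81), Lat (3.72), Flt1 (3.04), the immune checkpoint gene Lag3 (2.94) and Timp4 (2.94) lay above, and Gbp2 (-6.13), Anxa2 (-4.08), Oasl2 (-3.68), Lgals3 (-3.26) and the homeobox gene Meis2 (-3.06) below. From EpiSox2mL2 it differed for 1655 genes, but 1085 without the second P19 EC array, 1033 without the second P19-Sox2 array, 978 under median scaling and 946 over only these groups. Here Gsc (4.60), Fgf5 (4.50), Fam107a (3.75), Sox21 (3.69) and Lat (3.60) lay above, and Dppa5a (-5.31), Rbmxl2 (-4.80), Dnmt3l (-4.10), Gbx2 (-4.00) and Lgals3 (-3.94) below. The female and male EpiSC lines differed for 2875 genes. Gsc (3.80, SE 0.28), Gbp2 (3.52, SE 0.20), Myl1 (3.23, SE 0.20), Lhx1 (3.03, SE 0.24) and Anxa2 (3.02, SE 0.23) were on the female side, and Rbmxl2 (-4.86, SE 0.19), Vstm2l (-4.34, SE 0.25), Dppa5a (-4.11, SE 0.24), Dppa4 (-3.81, SE 0.16) and Ooep (-3.80, SE 0.17) on the male side.

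Over F9-Sox2, P19-Sox2 and EpiSox2mL2, in each of which Sox2 rose, 26 genes rose and 10 fell in common, against 3.64 and 1.99 expected under independence, and 22 and 8 of them were detected on both arrays of a group in each line. Beside Sox2 these rises included Dppa3 (log2 3.50, 1.04 and 2.27), the epithelial regulator Grhl2 (1.48, 0.49 and 0.85) and Gadd45a (0.81, 1.66 and 1.04). The falls included Sp5, Egln3 (-0.64, -0.89 and -1.18) and the transporter Slc13a4. Sp5 rose in EpiSox2mE1 and EpiSox2mE2, left out here. This count and its genes were chosen after seeing the data.

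With the arrays labelled Epi-Sox2f, in which Sox2 did not rise, as a further line, 10 genes rose in common, against 0.49 expected under independence. So neither this excess nor that of the 3 lines can be assigned to Sox2. The genes, chosen after their values were seen, were Cldn4, Anxa3, the endocytic gene Sh3gl2, the hormone gene Sct, Igf2 and the sulfotransferase Chst8. The EGFR inhibitor Errfi1, the actin-binding Tmsb4x, the fatty-acid carrier Fabp3 and the matricellular Ccn2 completed the 10. Fabp3 had the largest rise among them in F9-Sox2 (log2 2.64), Ccn2 in P19-Sox2 (2.65), Anxa3 in Epi-Sox2f (2.84) and Cldn4 in EpiSox2mL2 (1.60). A fall in all 4 lines was called for 0 genes, with 0.31 expected. In 3 or more of the lines 75 genes rose and 32 fell. F9 and P19 called 194 genes in common, and 67.0% moved in the same direction (r 0.08). In both, 87 rose and 43 fell, against 28.2 and 17.6 expected under independence. Calls in opposite directions were not set against an expectation, so this excess alone does not show a shared response. F9 and EpiSox2mL2 shared 338 genes with 54.7% in the same direction (r 0.05), and P19 and EpiSox2mL2 328 with 54.0% (r 0.01). The arrays labelled Epi-Sox2f shared 314 genes with F9 (49.7%), 323 with P19 (57.6%) and 765 with EpiSox2mL2, of which 33.6% moved in the same direction (r -0.11).

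The male Sox2 groups share EpiSCm as control, and its 2 arrays were not split, as each part would keep 1. EpiSox2mL2 and EpiSox2mE1 called 969 genes in common, 386 up and 382 down against 152 and 157 expected, with 79.3% in the same direction. Their correlation was 0.32 and their covariance 0.09, where simulated unchanged groups on the same controls gave 0.50 and 0.02, as for the pairs below. EpiSox2mL2 and EpiSox2mE2 called 871 in common, 330 up and 316 down against 143 and 162 expected, with r 0.29 and covariance 0.09. EpiSox2mE1 and EpiSox2mE2 called 807 up and 1021 down against 146 and 222 expected, with r 0.87 and covariance 0.29. Part of each excess may come from the shared controls. The simulation holds no changed genes, so its r does not show how much.

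The EpiSC controls also enter the EpiSC minus ESC differences, with the opposite sign. Genes called in both EpiSCf minus ESCf and Epi-Sox2f minus EpiSCf numbered 1758, and 24.8% had the same direction (r -0.24 and covariance -0.15, simulated -0.50 and -0.02). Both rose for 258 genes and both fell for 178, against 397 and 374 expected. For the male lines 35.3% of 1640 genes in EpiSox2mL2, 24.3% of 1933 in EpiSox2mE1 and 19.4% of 1934 in EpiSox2mE2 had the same direction. There r was -0.25, -0.30 and -0.36 (simulated -0.50) and covariance -0.16, -0.23 and -0.27 (simulated -0.02). Both rose for 351, 274 and 213 genes against 474, 485 and 454 expected, and both fell for 228, 195 and 163 against 290, 397 and 409. The simulated r has the same limit here.

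On an axis running from 0 in ESCf to 1 in EpiSCf over 2591 genes, ESCm stood at 0.19, F9 EC at 0.39 and F9-Sox2 at 0.36, P19 EC and P19-Sox2 at 0.69 each, EpiSCm at 0.80 and Epi-Sox2f at 0.92. EpiSox2mL2 stood at 0.66, EpiSox2mE1 at 0.69 and EpiSox2mE2 at 0.67, with SDs of 0.00 to 0.02 between arrays (n = 2). Over the 1206 genes higher in ESCf, EpiSox2mL2 stood at 0.65, EpiSox2mE1 at 0.75 and EpiSox2mE2 at 0.73. Over the 1385 genes higher in EpiSCf the order turned, at 0.69, 0.60 and 0.59. F9 EC stood at 0.48 and F9-Sox2 at 0.44 on the first set, and both at 0.25 on the second. An axis from the male pair cannot be told apart from the array set. On it EpiSox2mL2 stood at 0.90, EpiSox2mE1 at 0.87, EpiSox2mE2 at 0.84, EpiSCf at 0.58, P19 EC at 0.46 and F9 EC at 0.26.

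**Figure D3:**
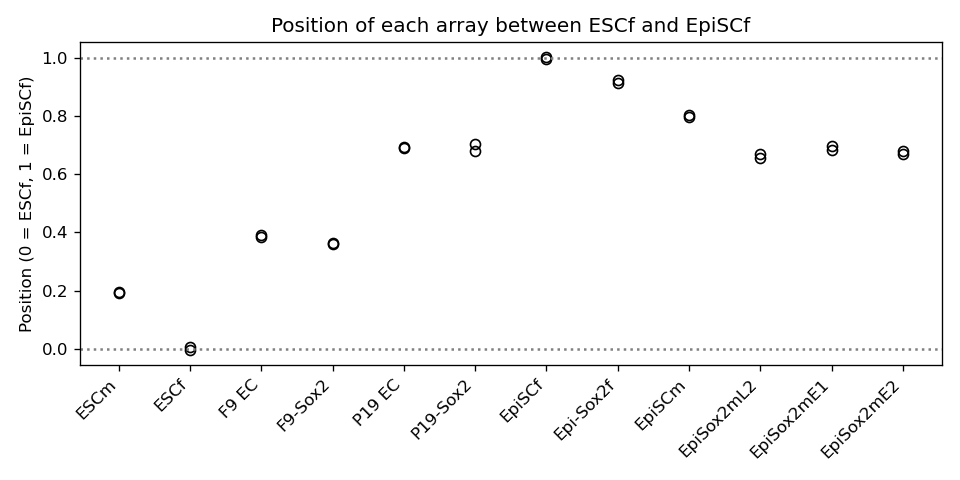
Position of each array between ESCf at 0 and EpiSCf at 1. P19 EC stood at 0.69 and F9 EC at 0.39 on average.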

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

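Each difference of effects held called genes and so met the rule for results that vary between groups. The change from parent to Sox2 line differed between F9 and P19 for 892 genes, between F9 and the female EpiSC line for 1956 and between F9 and the male line for 1476. Between P19 and the female and male EpiSC lines it differed for 1734 and 1655, and between those EpiSC lines for 2875, and the values with the female line cannot be assigned to Sox2, which did not rise there. The EpiSC minus ESC difference varied between the female and male pairs for 4525 genes, which cannot be told apart from the array set. With groups of 2, no array could be tested for distance from its group. All tests below were chosen after seeing the result they address.

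The arrays labelled Epi-Sox2f showed no Sox2 rise. Arrays of a line other than EpiSCf do not account for it, because Xist was detected and Eif2s3y absent in only 1 other group, EpiSCf itself. Nor does a probe blind to the transgene, since the same probe was called higher in 5 other Sox2 groups. An exchange of labels with EpiSCf is possible, as the other Sox2 probe was called lower (log2 -1.14). The kept probe was not (-0.18), so the test cannot tell. A fall of the cells' own Sox2 with a transgene holding the total is also possible. The gap between the Sox2 probes changed by 0.96 log2 units, and by 1.13 in F9-Sox2 and 1.21 in P19-Sox2 (SE 0.20 each). In GOF18 Sox2 groups, where the other probe lay near the detection limit, it changed by 0.11 to 0.44. Between EpiSCf and ESCf, without overexpressed Sox2, it changed by 0.98 (SE 0.20), so the test cannot tell. A loss of Sox2 overexpression in this line stays open and untested.

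Among the GOF18 groups, mesendoderm genes were highest in the ESC-medium arrays. An exchange of the EpiSox2mL2 label with 1 ESC-medium label does not account for it, because EpiSox2mE1 and EpiSox2mE2 differ by 213 genes and each differs from EpiSox2mL2 by 2787 or 3139. Nor does the scaling between arrays, as the highest adjusted p of the mesendoderm list over 3 other scalings and both comparisons was 3.2e-08. For feeder fibroblasts the test cannot tell, as ESCf, with no stated medium, may hold none. All 11 mesendoderm members called higher in EpiSox2mE1 lay lower in ESCf, where the fibroblast list median (log2 7.15) exceeded EpiSox2mE1's (6.49). Effects of medium and of line, which the design names together, also stay open and untested.

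Eif2s3y lay at background in F9 EC and F9-Sox2, which are labelled male. A female line with both X chromosomes active might show raised X-linked genes, and their median shift against ESCm was 0.19 in F9 EC, below 0.63 in ESCf and 0.44 in the male P19 EC, so the test cannot tell. A lost Y chromosome is another possible explanation, as 0 of the 4 Y-linked probes detected in ESCm or P19 EC were detected on both arrays of F9 EC or F9-Sox2, but a female origin would give the same value. Both explanations stay open.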

How the results depend on the processing

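Named genes, which include the largest changes, seldom turned. Of 10328 alternatives to 1256 gene results, 9723 stayed the same, 598 became weaker, 6 stronger and 1 reversed. Pou5f1 in EpiSox2mE1 against ESCm moved from 0.04, not called, to -0.47, called, under median scaling. Among all called genes, median scaling and the mean of a gene's probes turned the sign of some estimates, whether or not these were still called. Against ESCm these were 330 and 183 of 6227 in EpiSCm, 553 and 191 of 6007 in EpiSox2mE1 and 1156 and 198 of 5860 in EpiSox2mE2. The female and male difference had 388 and 123 of 4525, and any other comparison at most 3 and 40. Of 2016 alternatives to 336 list results, called or not, 1925 stayed the same, 52 became weaker and 39 stronger. Of the weaker, 33 were calls lost with an estimated correlation. Counts of genes stayed within 1.5 times in 305 of 352 alternatives and counts of lists in 74 of 84, and positions on the axis held in 70 of 138. The number of arrays, 2 a group, limits precision throughout, and dim signals limit the 8 GOF18 arrays, whose upper quartile was 139 to 183 against 249 to 379, though they detected more probes (10378 to 11415 against 9840 to 10748). Beyond what each alternative's construction shows (fewer genes, fewer arrays), the cause was not tested.

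Requiring at least 2-fold left 2591 genes in EpiSCf against ESCf, 3309 in EpiSCm against ESCm, 256 in F9-Sox2, 229 in P19-Sox2, 434 in Epi-Sox2f, 381 in EpiSox2mL2, 689 in EpiSox2mE1 and 673 in EpiSox2mE2. It left 793 and 872 for EpiSox2mE1 and EpiSox2mE2 against EpiSox2mL2, 3059 and 2971 against ESCm, 60 between them and 2211 in P19 EC against F9 EC. For differences of the change from parent to Sox2 line it left 516 (F9 and P19), 929 and 798 (F9 and female or male EpiSC), 782 and 811 (P19 and female or male EpiSC) and 1411 (female and male EpiSC). It left 2841 for the female and male EpiSC minus ESC difference. A fit over only the groups in the contrast, which have fewer residual degrees of freedom, called 574 in P19-Sox2, 676 in EpiSox2mL2, 1313 in EpiSox2mE1, 802 in EpiSox2mE2, 1690 for EpiSox2mE2 against EpiSox2mL2, 10 for EpiSox2mE2 against EpiSox2mE1 and 946 for P19 and male EpiSC. Only the dimmer arrays gave 1229 in EpiSox2mL2 and 33 for EpiSox2mE2 against EpiSox2mE1, and median scaling gave 978 for P19 and male EpiSC.

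Leaving out 1 array at a time, where the lone array is assumed to vary like the other groups, gave 469 to 505 genes in F9-Sox2, 480 to 742 in P19-Sox2, 1493 to 1768 in Epi-Sox2f, 1154 to 1737 in EpiSox2mL2 and 99 to 287 for EpiSox2mE2 against EpiSox2mE1. For P19 against female and male EpiSC it gave 1118 to 1389 and 1033 to 1528. Axis positions ranged over 0.192 to 0.207 in ESCm, 0.381 to 0.397 in F9 EC, 0.356 to 0.372 in F9-Sox2, 0.903 to 0.923 in Epi-Sox2f, 0.683 to 0.696 in P19 EC, 0.779 to 0.813 in EpiSCm, 0.644 to 0.674 in EpiSox2mL2, 0.672 to 0.700 in EpiSox2mE1 and 0.656 to 0.684 in EpiSox2mE2.

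Median scaling put ESCm at 0.186, F9 EC at 0.379, F9-Sox2 at 0.346, Epi-Sox2f at 0.898, P19 EC at 0.672, P19-Sox2 at 0.656, EpiSCm at 0.702, EpiSox2mL2 at 0.579, EpiSox2mE1 at 0.591 and EpiSox2mE2 at 0.549. Without background correction ESCm stood at 0.191, F9 EC at 0.366, F9-Sox2 at 0.345, Epi-Sox2f at 0.911, P19 EC at 0.687 and EpiSCm at 0.806. The authors' values gave 0.196, 0.402, 0.371 and 0.699 for ESCm, F9 EC, F9-Sox2 and P19 EC, and the mean of a gene's probes 0.197, 0.394, 0.368 and 0.700. With no fold threshold for axis genes, these 4 stood at 0.191, 0.397, 0.375 and 0.684, Epi-Sox2f at 0.904, EpiSCm at 0.814, EpiSox2mL2 at 0.685, EpiSox2mE1 at 0.705 and EpiSox2mE2 at 0.688. Over axis genes detected in both array sets the positions were ESCm 0.158, F9 EC 0.336, F9-Sox2 0.311, Epi-Sox2f 0.909, P19 EC 0.670, P19-Sox2 0.672, EpiSCm 0.780, EpiSox2mL2 0.624, EpiSox2mE1 0.655 and EpiSox2mE2 0.634. The axis from the male pair, across array sets, gave EpiSCf 0.585, F9 EC 0.261, F9-Sox2 0.244, Epi-Sox2f 0.544, P19 EC 0.464, P19-Sox2 0.444, EpiSox2mL2 0.903, EpiSox2mE1 0.869 and EpiSox2mE2 0.842.

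With an estimated correlation the number of lists called was 1 in F9-Sox2, 0 in P19-Sox2, 0 in Epi-Sox2f, 5 in EpiSox2mL2, 4 for EpiSox2mE2 against EpiSox2mL2, 4 and 4 for EpiSox2mE1 and EpiSox2mE2 against ESCm and 3 in P19 EC against F9 EC. Without the filter on dim probes it was 1 in Epi-Sox2f, and under median scaling 7 for EpiSox2mE2 against EpiSox2mE1.

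Median scaling moved the share of calls that were up from 54.7 to 65.5% in EpiSCf and from 59.0 to 38.7% in EpiSCm against ES cells, from 55.2 to 39.7% in F9-Sox2, 56.6 to 39.8% in P19-Sox2, 46.8 to 36.7% in Epi-Sox2f, 53.2 to 40.2% in EpiSox2mL2, 46.0 to 32.7% in EpiSox2mE1 and 43.6 to 12.0% in EpiSox2mE2. Against EpiSox2mL2 EpiSox2mE2 moved from 44.6 to 16.1%, against EpiSox2mE1 from 46.9 to 11.7%, and against ESCm EpiSox2mE1 moved from 58.1 to 31.7% and EpiSox2mE2 from 57.4 to 21.1%. The female and male difference moved from 45.5 to 77.9%. The median change of all genes then moved by 0.17 in EpiSCf and -0.35 in EpiSCm against ES cells, by -0.23, -0.15, -0.61 and -0.17 in EpiSox2mE2 against EpiSCm, EpiSox2mL2, ESCm and EpiSox2mE1, by -0.42 in EpiSox2mE1 against ESCm and by 0.57 in the female and male difference.

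With replicate number as a block no count of genes moved by over 1.5 times, F9-Sox2 giving 822 and P19-Sox2 879. Of the calls without it, the block kept 803 of 868 in F9-Sox2, 858 of 929 in P19-Sox2, 189 of 213 for EpiSox2mE2 against EpiSox2mE1 and at least 91.8% in every other comparison. Of the named genes, under the block Kremen1 (0.69) and Egln3 (-0.64) in F9-Sox2, Dnmt3b in P19-Sox2 (0.37), Cdkn2b for EpiSox2mE1 against EpiSox2mL2 (-0.50) and Lefty1 (-0.59) and Ccne1 (0.50) for EpiSox2mE2 against EpiSox2mE1 were not called. Neither was the neural and ectoderm list in EpiSox2mE1 (adjusted p = 0.054), while mesendoderm in P19-Sox2 was (adjusted p = 0.042), and the block changed no other call of a named gene or list. Same-number deviations of the 66 pairs of groups correlated at -0.19 to 0.18 with a median of 0.00, so a shared batch stays open. Crossing the numbers of EpiSox2mE2 in the block gave 2558, 3181 and 216 genes against EpiSCm, EpiSox2mL2 and EpiSox2mE1. A block by BeadChip was not run, because the files give no chip. The fits within 1 array set, the axis over genes of both sets, the crossed block and the fit without the arrays labelled Epi-Sox2f were added after seeing the data.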

Other observations

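Expression shifts of whole chromosomes separated the lines beyond the comparisons above. All of these tests and their limit, a mean log2 of at least 8 (3839 genes), were chosen after seeing the data, from 240 shifts over 12 comparisons and 20 chromosomes, and shifts are median log2 changes relative to all genes with camera's adjusted p at an estimated correlation. The 124 X-linked genes were shifted by 0.63 in ESCf against ESCm (adjusted p = 7.8e-07), with 91.9% above the median of all genes. In EpiSCf against ESCf they were shifted by -0.78 (adjusted p = 0.0012), and in Epi-Sox2f against ESCf by -0.45 (0.030). Both X chromosomes active in ESCf and 1 in EpiSCf could give these shifts, and Xist detected in EpiSCf alone of this pair fits that explanation.

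The 236 genes of chromosome 8 were shifted by 0.34 in F9 EC against ESCm (adjusted p = 0.0078, 74.2% above the median) and in F9-Sox2 (adjusted p = 0.0037, 72.5%). Other autosomes past the test were chromosomes 3 (-0.14), 9 (-0.11), 12 (0.13) and 16 (-0.20) in F9 EC, each with adjusted p = 0.0495, and chromosomes 3 (-0.23) and 6 (-0.21) in F9-Sox2. The 212 genes of chromosome 10 were shifted by 0.46 in EpiSCf against ESCf (adjusted p = 5.4e-05, 79.7% above the median) and by 0.41 in Epi-Sox2f (1.3e-04, 75.5%). An extra copy of these chromosomes in part or all of the cells may explain the shifts, and no DNA was measured. Chromosome 18 had first been named for EpiSCf by a misreading of the order of chromosomes, and its shift of -0.078 does not meet the prediction of an extra copy. Chromosome 16 was also past the test in EpiSCf (-0.27, adjusted p = 0.012).

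P19-Sox2 against P19 EC moved 11 of 19 autosomes past the test, with chromosome 13 the highest (0.24, 87.6% of its genes above the median) and chromosome 12 the lowest (-0.19). Chromosome 13 was also the lowest autosome in P19 EC against ESCm (-0.43, adjusted p = 0.068). In EpiSox2mE1 against EpiSCm chromosome 11 was shifted by -0.15 (adjusted p = 0.033), and in F9-Sox2 against F9 EC chromosome 6 by -0.15 (4.0e-04). The other Sox2 comparisons, in EpiSox2mL2, EpiSox2mE2 and Epi-Sox2f, called 0 autosomes against the parent line.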
